A study of Lactococcus cremoris subsp. cremoris MG1363 with 3 samples.

How the data were processed

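RNA from 3 independent cultures each of L. lactis MG1363 with pspxB+ (VES3910) and with pVE3916 (VES4075) was compared on 3 dual-colour spotted arrays. Per the labels' protocols, cells from 50 ml cultures were frozen, broken with glass beads in phenol/chloroform, and total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5. The labels put the pspxB+ strain in Cy5 on arrays 1 and 3 and in Cy3 on array 2. Array numbers follow accession order. Because each array carries a culture of either strain, every value is already a paired difference.

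The authors deposited 1 log ratio per spot and array, taken here as log2, after processing and normalizing the slides with MicroPrep, per the series design text. The image analysis, the background correction, the normalization curve, the spot filter, the version of the program, the base of the logarithm and the dye in the numerator are not given in the sources used here. The deposited log2 ratios had medians of 0.0005, 0.0026 and -0.0087 on arrays 1, 2 and 3, so each array was already centred near 0. A shift of all genes in one direction would have been removed by such centring. The largest absolute value was 8.94, which would be a ratio of 492 in base 2 and of 7647 in base e. Empty cells (3.66%, 1.34% and 3.76% of spots on the 3 arrays) were left as missing. Scanner intensities were not used here, so that dim spots could not be set apart from bright ones. Duplicate spots of a probe correlated across probes at r = 0.45, 0.54 and 0.39, and their differences had SDs of 0.79, 0.59 and 0.85, so that array 2 was the most precise.

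Locus tags and symbols were taken from the probe identifiers in the deposited table, which carry llmg tags of MG1363. The platform annotation table gave a single symbol for 854 of the 5376 spots, several for 0, and was not used for names. The identifiers covered 2295 genes, 1994 with 1 probe and 301 with several, and 1232 had a symbol. The 43 probes (86 spots) without a locus were kept out of the gene and list tests. The reference table at hand is of the strain KW2, so no coordinates were taken from it. All spots of a gene were averaged on the log2 scale within an array, and 2259 genes with a value on all 3 arrays were tested. How far different probes of a gene agreed was measured for 271 genes, with a median range between probe means of 0.28.

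The orientation rule was fixed before the data were examined: array 2 was to be turned if it correlated below 0 with the others, and it did. Whether the ratios run towards the pspxB+ strain was to be read from the dyes and set beside spxB, and where these did not settle it the rule asked for sizes and counts without direction. They did not, since read as Cy5 over Cy3 the ratios put spxB lower in the pspxB+ strain. In a departure from that rule, signs are given here relative to spxB, and the strain they point to is only called likely.

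The turned ratios were tested against 0 with limma (version 3.58.1, R 4.3.3), with lmFit and eBayes and no covariate. The prior had 2.94 degrees of freedom and an SD of 0.29, giving 4.94 degrees of freedom in all. P-values were adjusted after Benjamini and Hochberg over all genes, with a threshold of 0.05, and counts at the submitters' p of 0.001 were taken from the same fit. Intervals are 95% intervals of the moderated test. An exact sign-flip test of a single gene on 3 arrays cannot go below p = 0.25, so the p-values rest on the spread shared across genes. Gene lists were tested with camera (preset inter-gene correlation of 0.01), with an estimated correlation and with fry, over the 17 lists with at least 3 measured members. None passed after adjustment with the estimated correlation or in fry. With an estimated correlation, camera uses only the residual degrees of freedom, few with 3 arrays, so that hardly any list could pass. The p of ribosomal protein genes rose from 0.0162 to 0.101 (camera, unadjusted), although their estimated correlation of -0.019 was below the preset one. The list meant for prophage genes needed product names and had no members. The SDs in the text are over the 3 arrays.

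Genes were named by a rule fixed before the data were examined: spxB and the wall and envelope stress genes oatA, kinD, llrD, acmA, pgdA and xynD, up to 10 genes with the largest change in each direction past the adjusted threshold with 1 sign on all arrays, filled from the genes at p of 0.001, and up to 4 genes with the lowest p from each list. The members pepN, ctrA, ilvA, ilvB, ilvC, ilvD, ilvN, leuA, leuC, leuD, codY, arcD1, arcT, arcD2, mtlD and llmg_0640 were named after their values were seen. One member of the sugar uptake list is not reported here by name.

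The procedure was tested on simulated data: in 20 simulations of this comparison with 2259 genes, 200 of them changed, and the spread of the real arrays, 93.6% of genes changed by 2 on the log2 scale passed the adjusted threshold, 52.5% of those changed by 1 and 4.89% of those changed 1.5-fold. Of the calls, 4.31% were false. These shares depend on the assumed 200 changed genes. At the submitters' unadjusted p, 90.1% of simulated genes changed by 2 and 27% of those changed by 1 passed, fewer than at the adjusted threshold. In the real data the adjusted threshold was the stricter one, passing 18 genes against 33. The simulated shares at the adjusted threshold therefore likely overstate what it could detect in the real data. The alternatives were the opposite sign of array 2, centring, scaling between arrays (to equal median absolute values, since the planned limma scale function gave no values on ratios), leaving out each array, a dye term, other treatments of spots and of missing values, robust and weighted fits, a Cyber-T style and an ordinary one-sample statistic, and a 1.5-fold minimum. A median over spots, a test per probe and the CodY-linked list without the opp genes, with a preset and an estimated correlation, were added after seeing the data.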

Results

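Gene expression was compared between 2 strains of Lactococcus lactis MG1363, a plasmid-cured dairy lactococcus that serves as a laboratory model. One strain (VES3910) carried the plasmid named pspxB+ and the other (VES4075) carried pVE3916. SpxB belongs to the Spx family, small regulators that bind RNA polymerase, and the series title places the question in the O-acetylation of peptidoglycan, the cell wall polymer, and its resistance to hydrolysis. RNA came from 3 independent cultures of each strain, taken in mid-exponential growth (A600 of 0.3) in M17 broth with 0.25% glucose. Each of 3 dual-colour arrays carried both strains. The pspxB+ strain was in the Cy5 channel on arrays 1 and 3 and in the Cy3 channel on array 2. The arrays held 2688 probes spotted in duplicate. Of the 5376 spots, 5179 had a ratio on array 1, 5304 on array 2 and 5174 on array 3. After averaging the spots of each gene, 2259 of 2295 genes had a value on every array and were tested. Arrays give no read depth, and their number (n = 3) limited the precision.

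The gene taken as spxB, locus llmg_1155, showed one of the largest differences on the array. Its log2 ratio had a size of 4.57 on array 1, 4.23 on array 2 and 4.04 on array 3, a mean of 4.28 ± 0.27 (SD, n = 3), or 19.4-fold (limma moderated test, adjusted p = 0.00199). The array's identifiers give this locus the symbol trmA, which they also give to llmg_0640, and the assignment to spxB rests on prior knowledge of the locus. The other locus with that symbol, llmg_0640, had a mean of -0.03 ± 0.85 (SD, n = 3). As deposited, the spxB ratio was negative on arrays 1 and 3 and positive on array 2. No source used here states which dye was the numerator. If the ratio was Cy3 over Cy5, spxB was higher in the pspxB+ strain on all 3 arrays, and if it was Cy5 over Cy3, it was higher in the pVE3916 strain. The plasmid name makes the former the likely reading. Because the direction was read from spxB, this gene does not check the labels independently. Below, every ratio is turned so that spxB is positive, "higher" means higher in the strain in which spxB was higher (likely pspxB+), and all signs would turn together under the other reading. The base of the deposited logarithm is also unstated and was taken as 2, so that fold values depend on it.

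The arrays with opposite dyes gave mirrored values. Across the 2259 genes, the deposited ratios of array 2 correlated with the mean of arrays 1 and 3 at r = -0.53, and arrays 1 and 3 correlated with each other at r = 0.29. These correlations are across genes, which are not independent replicates. The turn of array 2 rests on this negative correlation. Had the deposited columns already been turned to 1 strain direction, differences between dyes would show in this way, and with array 2 left as deposited 0 genes passed (limma, 36 at an unadjusted p below 0.05). After array 2 was turned, 920 genes (40.7%) had the same sign on all 3 arrays, a share that the choice of the turn itself raises. The SD between arrays had a median of 0.27 over genes, and the median 95% interval of a gene's mean reached 0.42 to each side.

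**Figure D1:**
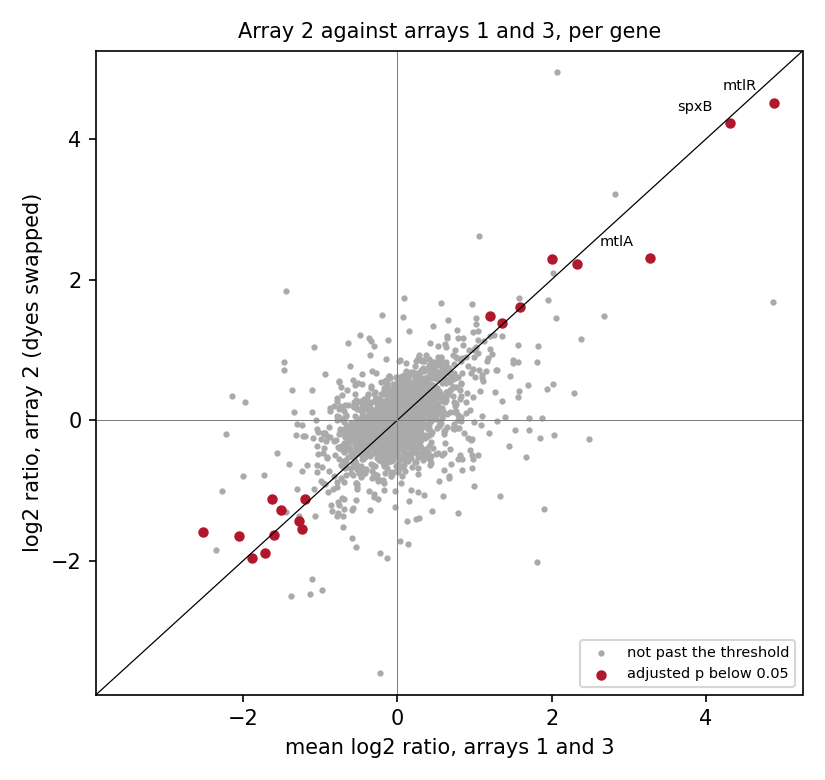
Each point is 1 of 2259 genes, with its mean log2 ratio on arrays 1 and 3 on the horizontal axis and its log2 ratio on the dye-swapped array 2 on the vertical axis, all turned so that spxB is positive; the line marks equal values. Red points are the 18 genes with an adjusted p below 0.05, and spxB and mtlR lie at the top right with 4.23 and 4.51 on array 2.

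The mannitol genes mtlR and mtlA, the autoinducer synthase gene luxS and 4 unnamed loci were higher together with spxB, while genes for oligopeptide uptake, the main autolysin and arginine deiminase were lower. In all, 18 genes differed between the strains at an adjusted p below 0.05 (limma moderated test, Benjamini-Hochberg over all genes), 8 of them higher and 10 lower, and all 18 by more than 2-fold. The largest difference was in mtlR (llmg_0023), a regulator of mannitol use, at 4.76 ± 0.32 (SD, n = 3) on the log2 scale, or 27-fold (adjusted p = 0.00199, limma). The adjacent mtlA (llmg_0022), the membrane component of the mannitol phosphotransferase system, was higher by 2.95 ± 0.76, although its probes differed, with means of 4.38 and 1.53. The lower of these probes was at 4.046, 0.151 and 0.395 on arrays 1, 2 and 3, so its mean came mostly from array 1. The unnamed loci llmg_2391, llmg_2520, llmg_2227 and llmg_2226 were higher by 2.29 ± 0.59, 2.10 ± 0.41, 1.60 ± 0.23 and 1.36 ± 0.11. The probes of llmg_2391 also differed, with means of 3.69 and 0.90. The gene luxS (llmg_0273) was higher by 1.29 ± 0.17.

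Among the lower genes, llmg_0454 had the largest change, at -2.21 ± 0.58 (SD, n = 3). It was followed by napC (llmg_0320) at -1.92 ± 0.43 and ps357 (llmg_0852) at -1.91 ± 0.45. The arginine deiminase gene arcA (llmg_2313) was at -1.78 ± 0.40 and the 2,3-butanediol dehydrogenase gene butB (llmg_1642) at -1.46 ± 0.29. The oligopeptide-binding protein gene oppA (llmg_0701) was at -1.61 ± 0.10, and the ATPase genes of the same transporter, oppF (llmg_0698) and oppD (llmg_0697), were at -1.34 ± 0.19 and -1.33 ± 0.18. The gene of the main autolysin, acmA (llmg_0280), whose enzyme cleaves peptidoglycan at cell separation, was at -1.43 ± 0.15, or 2.7-fold lower. The branched-chain amino acid transporter gene brnQ (llmg_0650) was at -1.18 ± 0.07. Apart from mtlR and spxB, the 16 calls had adjusted p-values between 0.0443 and 0.0452 (limma), close to the threshold, and the count was 2 without array 1, 2 without array 2 and 7 without array 3. It was 0 with an ordinary one-sample statistic, 2 with a dye term in the model, 70 with array weights, 185 with duplicate spots as correlated measurements and 23 after scaling the arrays to equal spread, then with 13 higher and 10 lower.

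**Figure D2:**
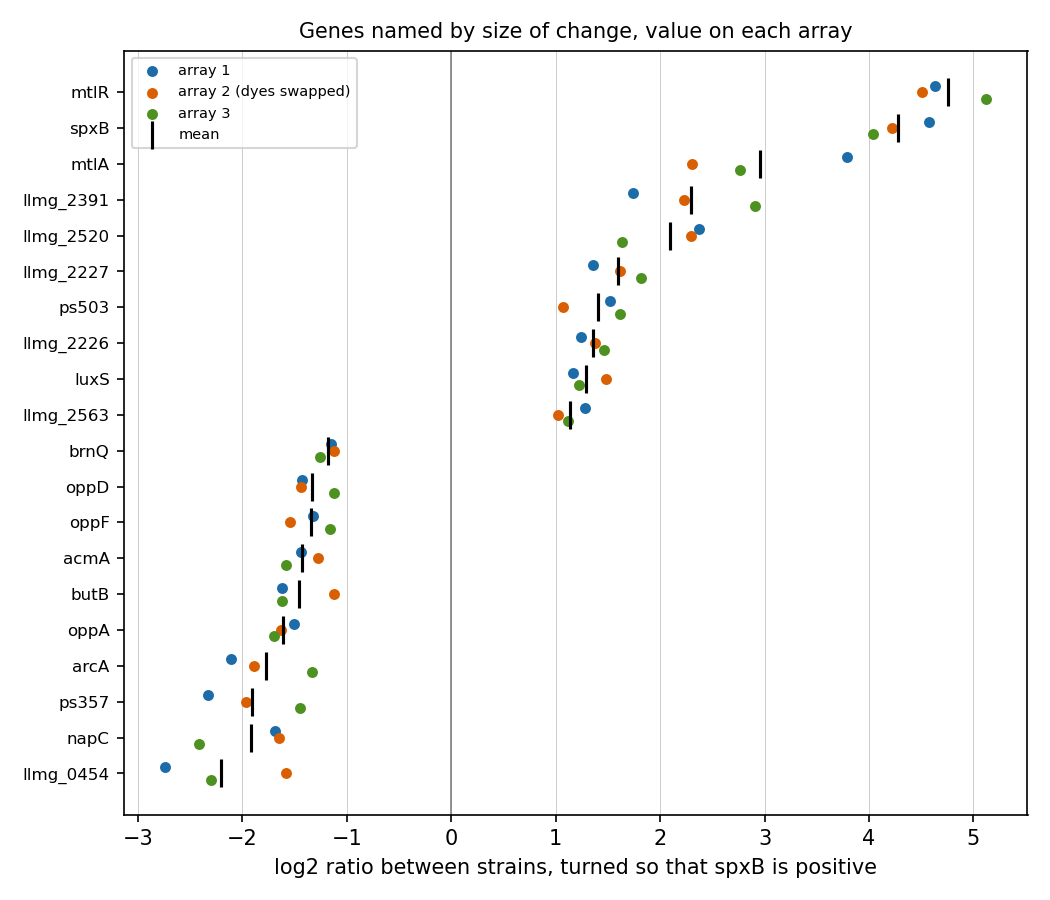
Log2 ratio (horizontal axis, turned so that spxB is positive) of the 18 genes with an adjusted p below 0.05 and of ps503 and llmg_2563, which passed an unadjusted p of 0.001 only; points are the 3 arrays and vertical bars their mean. All 3 arrays have the same sign for each gene, from mtlR at 4.76 to llmg_0454 at -2.21.

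The submitters called a gene altered at a Cyber-T Bayesian p of 0.001. At the same unadjusted p in the moderated test, 33 genes passed, 20 higher and 13 lower, where 2.26 are expected by chance among 2259. Without 1 array, 6 to 24 passed, 5 to 11 higher and 1 to 13 lower. A regularised statistic built after Cyber-T, with the background variance taken over all genes because no intensities were used, also gave 33 at that p, 19 higher and 14 lower. Among those that passed only this threshold were ps503 (llmg_2266) at 1.40 ± 0.29 and llmg_2563 at 1.14 ± 0.13 (SD, n = 3), and oppC (llmg_0700), a membrane component of the oligopeptide transporter, at -1.16 ± 0.17. At an unadjusted p of 0.05, 402 genes passed, against 113 expected. That count was 290 without array 1, 228 without array 2, 403 without array 3 and 218 with the Cyber-T style statistic.

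Genes linked to the nitrogen regulator CodY, a list of peptide uptake, peptidase and amino acid genes fixed before the data were examined, were lower as a group in the camera test with a preset correlation (adjusted p = 3.59e-06 over 17 lists). The call was lost with a correlation estimated from the arrays (adjusted p = 0.759, unadjusted p = 0.0474) and in fry (adjusted p = 0.0704). The estimated correlation was 0.029, close to the preset 0.01, and that form of camera has few degrees of freedom here. Its loss of the call therefore says little about correlation between the members. Of the list's 26 measured members, 20 had negative and 6 positive means, with a median of -0.45. In the test over all genes 3 were lower (oppA, oppD and oppF), none was higher and 23 did not pass. Adjusted over the list alone, 10 were lower and 1 was higher. The 10 included, beside the opp genes, ctrA at -0.88 ± 0.12, ilvB at -0.76 ± 0.18 and ilvC at -0.88 ± 0.38 (SD, n = 3). Beside ilvB and ilvC, the list's genes for branched-chain amino acid synthesis included ilvD, ilvA and leuA, at -0.45 ± 0.14, -0.47 ± 0.28 and -0.32 ± 0.48. The means of ilvN, leuC and leuD were positive, at 0.26 ± 0.82, 0.17 ± 0.24 and 0.11 ± 0.27. None of ilvD, ilvA, leuA, ilvN, leuC and leuD passed, also when adjusted over the list alone. The member that was higher, the aminopeptidase gene pepN (llmg_0319), had a mean of 1.57 ± 0.45, which came from 1 of its probes, at 3.01, while the other was at 0.13. The regulator gene codY itself was at 0.10 ± 0.17. Without the opp genes, 20 members remained, with a median of -0.28 (camera adjusted p = 0.0177, preset correlation), and with an estimated correlation this call too was lost (adjusted p = 0.759, unadjusted p = 0.0976).

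The arginine deiminase pathway, which yields ATP from arginine, was the only other list past the threshold with the preset correlation (camera adjusted p = 0.0155). The call was lost with an estimated correlation (0.619, camera adjusted p = 0.759) and in fry (adjusted p = 0.203). The 5 genes arcA, arcB, arcC2, arcC1 and arcD1 had means between -1.78 and -1.45, while arcT and arcD2 were at 0.18 ± 0.29 and 0.70 ± 1.04 (SD, n = 3). Only arcA passed the test over all genes, and all 5 passed adjusted over the list alone. Arrays differed widely here, with arcB at -2.01, -2.51 and -0.76 on arrays 1, 2 and 3. Without array 1 the camera adjusted p was 0.182, and over all alternatives it ranged from 0.000113 to 0.866.

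**Figure D3:**
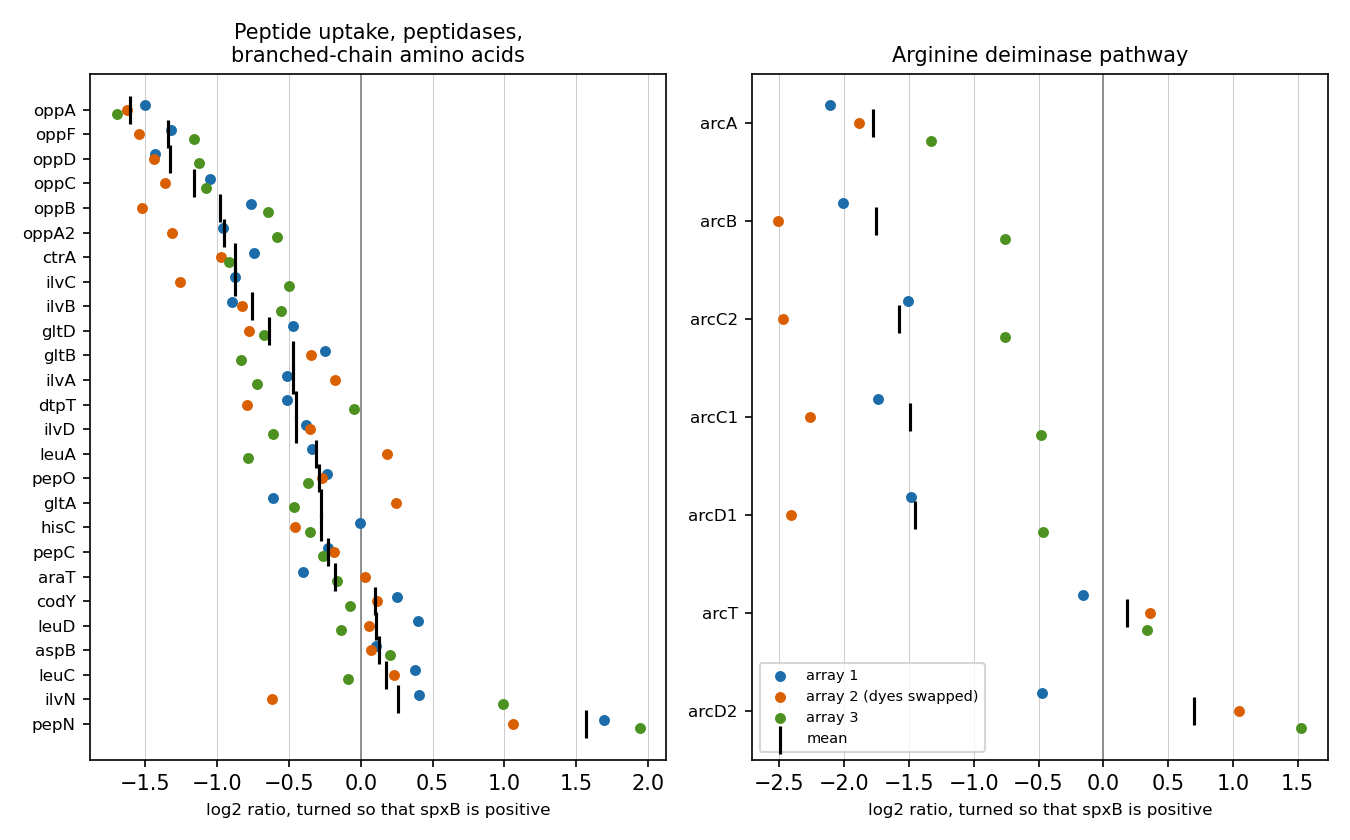
Log2 ratio (horizontal axes, turned so that spxB is positive) of the 26 measured genes of the CodY-linked list (left) and the 7 of the arginine deiminase list (right); points are the 3 arrays and vertical bars their mean. Of the left-hand genes 20 have a mean below 0, and pepN at 1.57 lies farthest above it.

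The listed cell wall genes other than acmA showed no difference past the threshold. Loci without a symbol could not be placed among wall genes. No array identifier carried the symbol oatA, the peptidoglycan O-acetyltransferase, so that this gene is not analysed here. Of the 12 genes for wall modification and hydrolysis (camera adjusted p = 0.544), acmA was lower, also adjusted over the list alone, and 11 did not pass, among them acmD at 0.51 ± 0.35, dltC at 0.53 ± 0.80 and dltD at -0.25 ± 0.03 (SD, n = 3). In fry this list was lower without passing (unadjusted p = 0.00867, adjusted p = 0.0704). The deacetylase gene pgdA was at -0.15 ± 0.26 and xynD at 0.06 ± 0.31. None of the 22 genes of peptidoglycan synthesis passed in limma, and 1 had an unadjusted p below 0.05 (list camera adjusted p = 0.79). The 2 with the lowest p were femD at 0.40 ± 0.20 and racD at 0.38 ± 0.23. The genes of the envelope stress system CesSR, kinD (llmg_1649) and llrD (llmg_1648), were at 0.05 ± 0.19 and -0.05 ± 0.28. Of the 16 genes linked to that system, spxB was higher and 15 did not pass. Adjusted over the list alone, spxB was higher and llmg_0165 (-0.91 ± 0.25) and dxsB (-0.56 ± 0.04) were lower. The probes of llmg_0165 differed, with means of -1.46 and -0.17. For this list the median was -0.08 and the mean 0.08, so that these differ in sign (camera adjusted p = 0.677). The positive mean came from spxB, by which all ratios were turned, and without it the mean of the other 15 was -0.20.

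Of the 27 sugar uptake genes, mtlR and mtlA were higher in the test over all genes. Adjusted over the list alone, 5 were higher, among them mtlF at 2.28 ± 1.10 and mtlD at 3.81 ± 2.18 (SD, n = 3). The list's median was -0.19 and its mean 0.36, and camera placed it below the other genes without passing (adjusted p = 0.903). Ribosomal protein genes had a median of -0.12, with 35 of 48 negative, no member past the threshold in limma, 6 with an unadjusted p below 0.05 (1 higher and 5 lower) and a camera adjusted p = 0.0916. The lowest p-values were those of rplC at -0.93 ± 0.40 and rpsR at -0.84 ± 0.34. Heat shock chaperone and protease genes had 11 of 14 negative, none past the threshold in limma and 2 with an unadjusted p below 0.05 (camera adjusted p = 0.165), with dnaK at -0.75 ± 0.46 and hslB at -0.54 ± 0.20. Among all 2259 genes tested, 402 had an unadjusted p below 0.05 (limma), so the counts of ribosomal and chaperone genes below it are no excess.

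None of the members passed the limma test over all genes in the remaining lists, apart from spxB in that of the Spx family and RNA polymerase, whose median of -0.02 and mean of 0.50 differ in sign (camera adjusted p = 0.448). Without spxB the mean of that list was 0.03. At an unadjusted p below 0.05, where 402 of all 2259 genes stood, were 3 thiol and oxidative stress genes, 2 glycolytic genes, 1 ATP synthase gene, 1 competence gene, 1 fatty acid gene, 4 cell division genes and no gene of purine or pyrimidine synthesis. In that list rpoB, the RNA polymerase beta subunit, was at 0.10 ± 0.26 and rpoE at 0.19 ± 0.37 (SD, n = 3). Thiol and oxidative stress genes had a median of 0.03 and a mean of -0.07, which differ in sign, with noxB at -0.59 ± 0.06 and gpo at -0.54 ± 0.26 (camera adjusted p = 0.679). Genes of purine synthesis had a median of -0.27 (camera adjusted p = 0.257), with purC at -1.31 ± 1.88, and those of pyrimidine synthesis a median of 0.13 (camera adjusted p = 0.448), with pyrDA at 0.46 ± 0.46. Glycolytic genes had a median of -0.02 (camera adjusted p = 0.876), with enoB, on a locus marked as a pseudogene, at -0.56 ± 0.09 and pfk at 0.46 ± 0.08. The probes of enoB differed, with means of -0.82 and -0.14. ATP synthase genes had a median of -0.21 (camera adjusted p = 0.229), with atpC at -0.47 ± 0.30. That list passed without array 3 (camera adjusted p = 0.0128) and with array weights (camera adjusted p = 0.0226), both at the preset correlation. With an estimated correlation over all arrays, 0.869 and far above the preset 0.01, its camera adjusted p was 0.759. The competence list had a median of -0.05 (camera adjusted p = 0.679), with comGC at -1.06 ± 0.34, its 1 member past the threshold adjusted over the list alone. Fatty acid synthesis had a median of -0.02 (camera adjusted p = 0.903), with acpA at -0.98 ± 0.45, and cell division a median of -0.15 (camera adjusted p = 0.679), with ftsE at -0.52 ± 0.19 and ftsA at 0.48 ± 0.11.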

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

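The median over spots, the test per probe and the list without opp genes were chosen after the data were seen. The difference in spxB kept its sign in all settings run (4.13 to 4.40 without 1 array). It had to, since all ratios were turned by spxB and its values were alike on all arrays. The difference in spxB lost the threshold with the opposite sign of array 2 (1.46) and with the ordinary one-sample statistic (4.28, adjusted p = 0.18). The 18 calls became 0 with the opposite sign of array 2, where the counts of higher and lower genes, of genes at p of 0.001 and of lists were all 0 as well (limma, with 36 genes at an unadjusted p below 0.05), and 0 with the ordinary one-sample statistic, which left 6 genes at p of 0.001, 3 in each direction, and 316 at 0.05. With a dye term 2 genes were called, both higher, and 8 passed p of 0.001, 5 higher and 3 lower. That fit has 1 fewer residual degree of freedom. With genes on at least 2 arrays 2 were called, both higher. With the first spot of each gene 3 were called, all higher, and 11 higher genes passed p of 0.001. More genes were called with array weights (70, of which 37 higher and 33 lower, and 54 at p of 0.001 with 24 lower), where array 2 had a weight of 2.34 against 0.72 and 0.59. With duplicate spots as correlated measurements (correlation 0.67) 185 were called, 97 higher and 88 lower, and 91 passed p of 0.001, 49 higher and 42 lower. That fit takes spots of 1 array as partly independent. The Cyber-T style statistic called 29, of which 17 higher, and scaling between arrays called 23, of which 13 higher, with 16 of the 18 among them. The cause of these changes was otherwise not tested. The median over spots called 23 genes, including all 18, and the test per probe 22. Without 1 array, 2 to 7 genes were called (2 to 4 higher, 0 to 3 lower), 6 to 24 passed p of 0.001 (5 to 11 higher, 1 to 13 lower) and 1 to 3 lists passed. The lists went to 0 with an estimated correlation, with or without the opp genes, and to 0 with fry. The test with an estimated correlation could hardly pass any list with 3 arrays.

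Among the named genes, none past the adjusted threshold changed sign in any setting run. Their 1 sign on all arrays made that outcome nearly certain, since every setting used the same arrays. Some genes that had not passed changed sign, among them arcC2, arcC1, arcD1 and arcT of the arginine deiminase list. With the opposite sign of array 2, pgdA became 0.085, xynD -0.21, acmD -0.065, racD -0.011, arcC2 0.071, arcC1 0.014, arcD1 0.16, arcT -0.060, hisC 0.032, pgk -0.031, atpC 0.071, atpB 0.094, atpA 0.082, atpG 0.11, accB -0.033 and plsX -0.049, and the ATP synthase and fatty acid lists changed direction (adjusted p = 0.323 and 0.557). Without 1 array, kinD ranged from -0.036 to 0.16, llrD from -0.19 to 0.088, rpoE from -0.008 to 0.36, rpoB from -0.045 to 0.19, xynD from -0.11 to 0.19, comFC from -0.20 to 0.96, leuD from -0.040 to 0.23, ilvN from -0.11 to 0.70 and llmg_0640 from -0.42 to 0.42, and the adjusted p of the sugar, fatty acid and glycolysis lists, whose direction changed, ranged from 0.882 to 0.957, 0.828 to 0.867 and 0.694 to 0.98. With a dye term llrD was 0.024 and the sugar list changed direction (adjusted p = 0.926). With the first spot of each gene kinD was -0.036, xynD -0.29, llrD 0.093, dltC -0.069, rpoB -0.0014, comGB 0.060, leuC -0.16 and leuD -0.21, and the glycolysis list changed direction (adjusted p = 0.937). With array weights kinD was -0.038, llrD 0.080, ilvN -0.16 and llmg_0640 0.055, and the ATP synthase list passed (adjusted p = 0.0226), as it did without array 3 (0.0128), both at the preset correlation. With an estimated correlation over all arrays its adjusted p was 0.759. In fry the envelope stress and sugar lists were higher, not lower (adjusted p = 0.499 and 0.0704). No other pairing was fitted, since the test already uses the difference between the strains within each array. Of the planned trend or robust eBayes only the robust one was run, since no intensities were used. The lists were not run with duplicate spots, with genes on at least 2 arrays or with robust eBayes. A change of 1.5-fold was rarely detectable with 3 arrays, as 4.89% of simulated changes of that size were called.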

Other observations

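The tests in this part were chosen after the data were seen, except the counts over sign patterns and the comparison of neighbouring loci with neighbouring probes.

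Genes with consecutive locus tags often differed in the same direction, a pattern first noticed among the largest changes. At an unadjusted p below 0.05, 83 genes lay in 22 runs of at least 3 consecutive loci with 1 sign, 14 higher with spxB and 8 lower. When the loci were shuffled 1000 times, the mean number of runs was 2.23 and the highest 8 (permutation p = 0.001, the smallest these permutations can give). The longest run held 6 genes, from tmk (llmg_0415), thymidylate kinase, and holB to llmg_0420, with a median of 0.74. Outside the mtl, opp and arc runs no member passed the adjusted threshold in limma. The run of hisI, hisF and hisA had a median of -0.66, that of llmg_1293, hisB, hisD, hisG and hisZ one of -0.46, and that of nupC, nupB and nupA one of -0.80. The gene hisC, next to the second of these, was at -0.28 ± 0.24 (SD, n = 3). Runs with positive means included mtsB, mtsC and mtsA (median 0.56), the 2-component genes kinG and llrG with tyrA and llmg_1930 (0.93), and ntd, llmg_0479 and dukA (1.29). The runs of mtlA to ps130, opp and arc genes had medians of 2.95, -1.33 and -1.58.

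Genes with symbols of ps and 3 digits, taken here as prophage genes, were grouped by their first digit. The group with ps3 symbols (48 genes between llmg_0790 and llmg_0852) had a median of 0.27, with medians of 0.23, 0.21 and 0.22 on arrays 1, 2 and 3, 31 genes higher and 17 lower. At an unadjusted p below 0.05, 13 were higher and 1, ps357, was lower. Camera gave an adjusted p = 0.00738 over 6 such groups with the preset correlation. With an estimated one, which has little power with 3 arrays, the camera adjusted p was 0.358. The genes of the group lie close together, so the preset correlation of 0.01 may be too low for them. The call with it may therefore overstate the evidence. The ps4 group (53 genes) had a median of 0.03 and an adjusted p = 0.421. The smaller ps5 and ps6 groups (15 and 9 genes) had medians of 0.15 and 0.24, nearer that of ps3, and did not pass (camera adjusted p = 0.199 and 0.421, preset correlation). The ps1 and ps2 groups had medians of 0.01 and -0.05.

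Co-transcription of neighbouring genes in operons is a candidate explanation of the runs, and it was not tested, since strands and distances were not used. A shared error of spots printed side by side is the technical one, with the probe number standing in for the print position. Pairs of consecutive loci whose probe numbers lay more than 20 apart correlated at r = 0.158 (bootstrap 95% interval 0.0931 to 0.229, 1399 pairs). Probes with different prefixes before the number were counted among these, although their print distance is unknown. Pairs with consecutive probe numbers and distant loci correlated at r = 0.0695 (-0.0745 to 0.219, 269 pairs). The intervals overlap, so a printing error could not be excluded. Pairs of consecutive loci with probe numbers within 2 correlated at r = 0.424 (bootstrap 95% interval 0.3 to 0.552, 1008 pairs). This interval lies above that of consecutive loci with distant probe numbers, so closeness in probe number went with a higher correlation.

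A gene-specific dye bias, by which a gene reads higher in 1 dye whatever the strain, could give large ratios. It gives spxB, named before the data were examined, no reason to rank high, yet spxB ranked 3 of 2259 genes by size on arrays 1 and 3 and 3 on array 2 (0.133% of genes), with opposite signs as deposited. If llmg_1155 is the gene that pspxB+ carries, the columns then run by dye, and this sets the turn of array 2 without the other genes. Of 100 other genes with 1 sign and the largest mean on arrays 1 and 3, 80 kept their sign on array 2 so turned (80%, exact 95% interval 70.8% to 87.3%). That interval takes the genes as independent, which neighbouring loci were not, so it is likely too narrow. Given that turn, which rests on spxB alone, the share of 80% argues against dye bias as the whole cause. Without it the share says nothing on dye bias, since it largely restates the negative correlation of array 2 with the others. A contribution to single genes stays open, although no gene's dye term passed an adjusted p of 0.05 in limma, a test with 1 residual degree of freedom before moderation.

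With 3 arrays there are only 4 sign patterns, too few for a share under 0.05. The pattern used, chosen as the one on which the arrays go together, gave 18 genes at the adjusted threshold and 33 at p of 0.001, and each of the others gave 0, so that 1 of the 4 patterns reached either count. For the lists, 2 of the 4 patterns gave as many, and the highest of the others was 2.

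The probes of pepN disagreed more than those of any other of 271 genes, by 2.88 on the log2 scale. Probe mg8659 was at 3.38, 2.48 and 3.15 on arrays 1, 2 and 3, and probe MG1132 at 0.005, -0.36 and 0.73. Scatter between spots was simulated for all 271 genes, with a whole difference between duplicate spots as the error of 1 spot. This overstates the scatter where the errors of duplicates are independent, and leaves out any error they share. Errors were drawn for each array separately from the differences of all probes, so a probe noisy on every array was not simulated. The largest range reached that of pepN in 2.5% of 1000 simulations (highest 4.21). This argues against scatter of the simulated kind as the whole cause, and leaves a noisier probe open. One probe may bind another transcript that differs between the strains, for example one from a plasmid. The mean of 0.125 of the unmoved probe is what this needs, but probe and plasmid sequences were not used here, so it stays open beside a real change in part of the gene. The next largest ranges were those of mtlA (2.85), llmg_1254 (2.83), llmg_1803 (2.80) and llmg_2391 (2.79).

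Of the 43 probes without a locus, 41 had a value on all arrays. None passed an adjusted p of 0.05 in limma over all probes, and 2 passed an unadjusted p of 0.05.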
